A study of Mus musculus with 39 samples.

How the data were processed

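Poly-A RNA was sequenced on an Ion Torrent Proton instrument from male C57BL/6J mice aged 22 weeks, in 39 libraries that the labels assign to epididymal white adipose tissue (eWAT, 19 libraries) or quadriceps muscle (20 libraries). The labels give each library a juvenile diet during weeks 6 to 7 (control diet, CD, with 10% of calories from fat, or high-fat diet, HFD, with 45%) and a feeding state over the last 16 h (fed or fasted), which makes 8 groups of 4 to 6 libraries. The deposited files hold 1 integer read count per Ensembl gene and library, without normalization. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie2 2.2.5 and HTSeq 0.6.0 were used with genome build GRCm38. The role of each tool, the annotation release, the strand setting and the alignment quality threshold are not given in the sources used here. Each file ended with 5 summary lines for reads not assigned to a gene, which were left out of library sizes. The remaining 45232 gene identifiers were looked up in GENCODE release M21, where 44585 had a symbol and 647 had none. Positions are 1-based on GRCm38.

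Between 6199586 and 14993394 reads were counted per library, from 6199586 to 14596745 in libraries labelled eWAT and from 6730219 to 14993394 in quadriceps. These were 18.4% to 39.9% of the reads listed in each file. Up to 44.6% fell outside the counted features. A further 11.4% to 32.8% were set aside for low alignment quality and 2.9% to 16.0% for aligning to more than 1 place. Gm42418, a gene that overlaps ribosomal RNA sequence, lay between 24236 and 291585 CPM on plain library sizes. Reads carried no molecular identifiers, so counts are not independent molecules.

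Genes were kept by the filterByExpr rule of edgeR 4.0.16 within each tissue, which left 16603 genes in eWAT and 12213 in quadriceps. Library sizes were scaled by TMM. A quasi-likelihood negative binomial model with robust dispersion estimates was fitted in edgeR with 1 mean per group, and 7 contrasts per tissue were tested: juvenile diet as the average over feeding states, in fed mice and in fasted mice; fasting as the average over juvenile diets, after juvenile CD and after juvenile HFD; and the interaction of diet and fasting. A fit of all 39 libraries tested the difference between tissues in the fasting response over 17083 genes. Adjusted p is the Benjamini-Hochberg value over all tested genes of a contrast, with a threshold of 0.05, and all tests were two-sided. The common biological coefficient of variation was 0.779 in eWAT and 0.203 in quadriceps. The fit of all 39 libraries shares 1 spread, so its SE may be too small for eWAT and too large for quadriceps. Fold changes are log2 with their standard error (SE). Group levels are CPM (read counts scaled to a common library size) on TMM-scaled library sizes with their SD, and marker sums are CPM on plain library sizes.

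A collection of 41 gene lists for pathways and cell types was fixed in advance. List members were also adjusted over the list alone. Lists with at least 5 tested genes were compared with the remaining genes by camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and by fry. Genes were named by a fixed rule. For the average contrasts these were the 10 largest changes per direction among protein-coding genes past the threshold with an average log2 CPM of at least 2, or, where none passed, the 5 smallest p per direction; up to 3 members with the smallest p from each described list; and 10 genes of interest in each tissue where tested. For the other contrasts they were the 5 smallest p per direction past the threshold. Genes outside this rule are marked as chosen after their values were seen. Of the genes this rule names, 3 are not reported here. The gene lists, contrasts, naming rule and first set of alternatives were chosen before the data were examined; further marker lists, among them hepatocyte and testis genes, were written after the data were seen.

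Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, all 39 libraries in one fit, an estimated correlation for the lists, and leaving out each library in turn. Alternatives added after seeing the data were an eWAT fit of the libraries with an epididymal marker sum above 1000 CPM, marker sums as covariates, an offset removing each library's trend with GC content and exonic length, and leaving out Gm42418. Other splits of the samples were drawn with a fixed seed. Adipocyte transcripts in eWAT were also compared with each other within a library, as log2 CPM with a prior count of 0.5 minus the mean of the other listed transcripts, by exact permutation, within juvenile diets for fasting and within feeding states for juvenile diet. The models were tested on simulated data in which 200 genes were changed. With a 2-fold change, 79.1% were recovered for juvenile diet in quadriceps and 11.9% in eWAT, and with a 4-fold change 98.5% and 50%; none was called in the wrong direction. Calculations used R 4.3.3 and Python 3.11.15, with matplotlib 3.10.9 for the plots.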

Results

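Gene expression was measured by poly-A RNA sequencing in epididymal white adipose tissue (eWAT) and quadriceps muscle of male C57BL/6J mice. The mice ate chow, then a control diet (CD, 10% of calories from fat) or a high-fat diet (HFD, 45%) from week 6 to week 7, then chow until week 10, and from then all ate the same HFD until week 22. Some were fasted for 16 h before collection. The libraries labelled eWAT numbered 6 (CD fasted), 4 (CD fed), 5 (HFD fasted) and 4 (HFD fed), and those labelled quadriceps 6, 4, 6 and 4. Between 6199586 and 14993394 reads were counted per library. The design asks what a single week of HFD in juvenile life leaves behind in the adult tissue, and whether it alters the response to fasting. The labels do not say whether each library came from a separate animal, so p-values measure the spread among these samples.

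Among the libraries labelled eWAT, 13 of 19 carried abundant transcripts of the epididymis, the sperm duct beside this fat pad. The summed level of 22 epididymal markers ran from 21510 to 73743 CPM (median 51194) in these 13 libraries. It ran from 10.3 to 54.8 CPM in the other 6 and reached at most 1.85 CPM in quadriceps. Gpx5, a secreted epididymal peroxidase, lay between 1687 and 29108 CPM in the 13 libraries and between 1.89 and 16.6 CPM in the other 6. Lcn5, an epididymal lipocalin, lay between 1350 and 10783 CPM against at most 6.15 CPM. Adipocyte markers went the other way. The sum of 20 markers had a median of 3894 CPM (1932 to 25714) in the 13 libraries and 66021 CPM (8086 to 76180) in the other 6. In quadriceps it was 1888 CPM (1193 to 3494), but it does not measure fat alone there. In HFD fasted replicate 3 of quadriceps the sum was 2351 CPM with Adipoq at 0.21 CPM. The epididymal transcripts were spread unevenly over the groups: 3 of 6 CD fasted, 4 of 4 CD fed, 4 of 5 HFD fasted and 2 of 4 HFD fed libraries carried them. Hepatocyte transcripts reached 164885 CPM in HFD fasted replicate 4 and 46175 CPM in CD fasted replicate 1, with Alb alone at 75953 and 16167 CPM. Testis transcripts reached 9577 CPM in HFD fasted replicate 1, and fast muscle fibre transcripts 2483 CPM in HFD fed replicate 3. Adipocyte transcripts varied widely within groups. In CD fasted (n = 6), CD fed (n = 4), HFD fasted (n = 5) and HFD fed libraries (n = 4), Adipoq averaged 2157 ± 1815, 179 ± 78.3, 215 ± 175 and 1774 ± 1784 CPM (SD). In the same order Lep averaged 189 ± 246, 73.0 ± 25.5, 22.5 ± 29.3 and 770 ± 755 CPM, and Fasn 515 ± 231, 993 ± 141, 506 ± 160 and 4065 ± 4358 CPM.

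**Figure D1:**
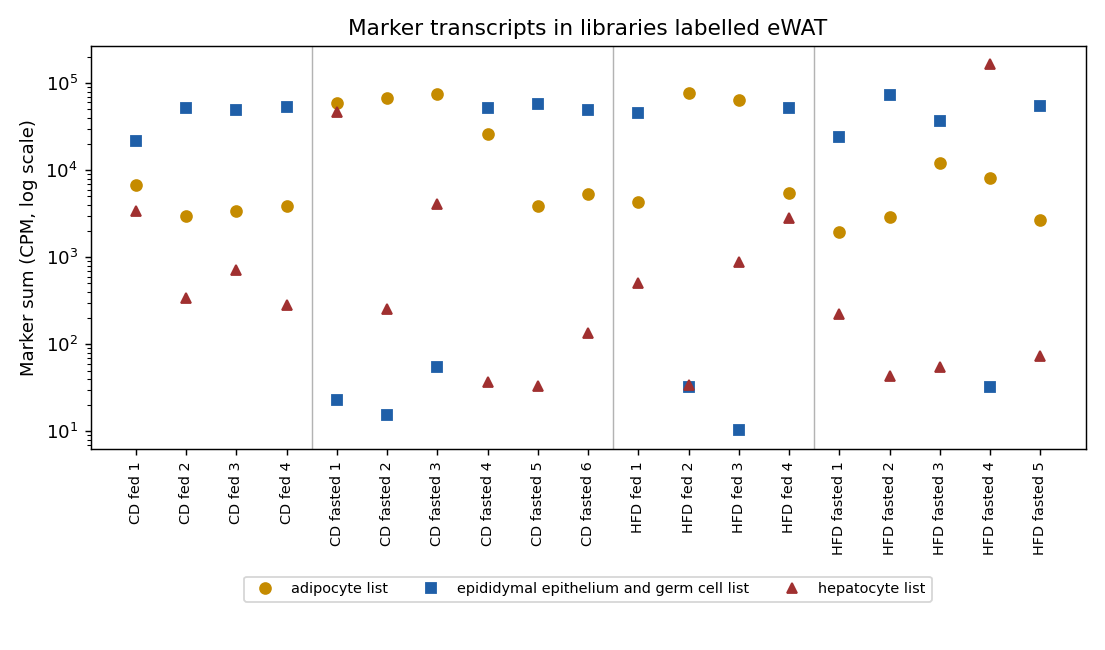
Summed CPM of the adipocyte, epididymal and hepatocyte marker lists (log axis) in each of the 19 libraries labelled eWAT, 1 point per list and library. In 13 libraries the epididymal sum is at or above 21510 CPM, and in the other 6 it is at or below 54.8 CPM.

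Transcripts of the muscle ubiquitin ligases Trim63 and Fbxo32, and of Pdk4 and Depp1, were higher in fasted quadriceps. Trim63, a ubiquitin ligase of muscle atrophy (ENSMUSG00000028834, 4:134315120-134329629), averaged 1928 ± 517 CPM (SD, n = 6) in fasted and 162 ± 35.8 CPM (n = 4) in fed mice after juvenile CD. After juvenile HFD the averages were 1894 ± 311 CPM (n = 6) and 159 ± 12.5 CPM (n = 4). Averaged over juvenile diets it rose 11.9-fold (log2 3.58 ± 0.14 SE; edgeR quasi-likelihood, adjusted p = 1.55e-17; 12 fasted and 8 fed libraries). Its partner ligase Fbxo32 (ENSMUSG00000022358, 15:58175879-58214932) rose 9.28-fold (3.21 ± 0.15; edgeR adjusted p = 1.76e-14). Pdk4, which holds pyruvate back from oxidation (ENSMUSG00000019577, 6:5483351-5496309), rose 16.7-fold (4.06 ± 0.32; edgeR adjusted p = 2.45e-08). The largest rise, 91.1-fold, was that of the FoxO-responsive gene Depp1 (ENSMUSG00000048489, 6:116650609-116652794; 6.51 ± 0.30; edgeR adjusted p = 1.2e-11). This ranking covers protein-coding genes past the threshold with an average log2 CPM of at least 2. For all 4 genes each of the 12 fasted libraries lay above each of the 8 fed ones. Depp1 lies inside the span of Rassf4 (6:116633008-116673952), and since the strand setting of the counts is not known, reads of the pair cannot be fully separated.

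The other large rises in this ranking were those of the acyl-CoA thioesterase Acot1 (4.86 ± 0.57), Cebpd (3.75 ± 0.23), Ddit4 (3.65 ± 0.35), Il6ra (3.59 ± 0.25), Cidea (3.56 ± 0.84), the lipase inhibitor Angptl4 (3.53 ± 0.30) and Arrdc2 (3.49 ± 0.22). Their edgeR adjusted p ran from 1.19e-10 for Cebpd to 0.00308 for Cidea. The steepest fall under the same limits was that of Nmrk2, a nicotinamide riboside kinase of muscle (ENSMUSG00000004939, 10:81198170-81202051), which was 31.8-fold lower in fasted mice (-4.99 ± 0.33; edgeR adjusted p = 3.18e-09). Mrtfa, an actin-regulated cofactor of serum response factor (ENSMUSG00000042292, 15:81012281-81190757), was 7.48-fold lower (-2.90 ± 0.13; edgeR adjusted p = 4.57e-16). For both genes each of the 12 fasted libraries lay below each of the 8 fed ones. Cish (-3.49 ± 0.52), Ccnd1 (-3.08 ± 0.18), Pdzd7 (-2.86 ± 0.26), Tnfaip2 (-2.68 ± 0.12), 6430571L13Rik (-2.59 ± 0.14) and Fam78a (-2.59 ± 0.17) fell as well. Apoa1 (-4.04 ± 1.53; edgeR adjusted p = 0.0469) and Alb (-3.64 ± 1.37; adjusted p = 0.0465) rested on CD fed replicate 3, whose hepatocyte marker sum was 799 CPM. Without it their changes were -1.72 and -0.80 and neither passed. In total 4588 of 12213 tested genes passed in edgeR, 2345 higher and 2243 lower. In one fit of all 39 libraries 1589 passed, and 3016 with the adipocyte marker sum as a covariate, a setting chosen after seeing the data. The first of these shares 1 spread across tissues, so its SE may be too large for quadriceps. The marker sum is not a measure of fat alone. In HFD fasted replicate 3 it was 2351 CPM while Adipoq was 0.21 CPM and Cfd 8.17 CPM. It also holds Pnpla2, itself higher in fasted mice, so this covariate can remove part of the fasting response.

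**Figure D2:**
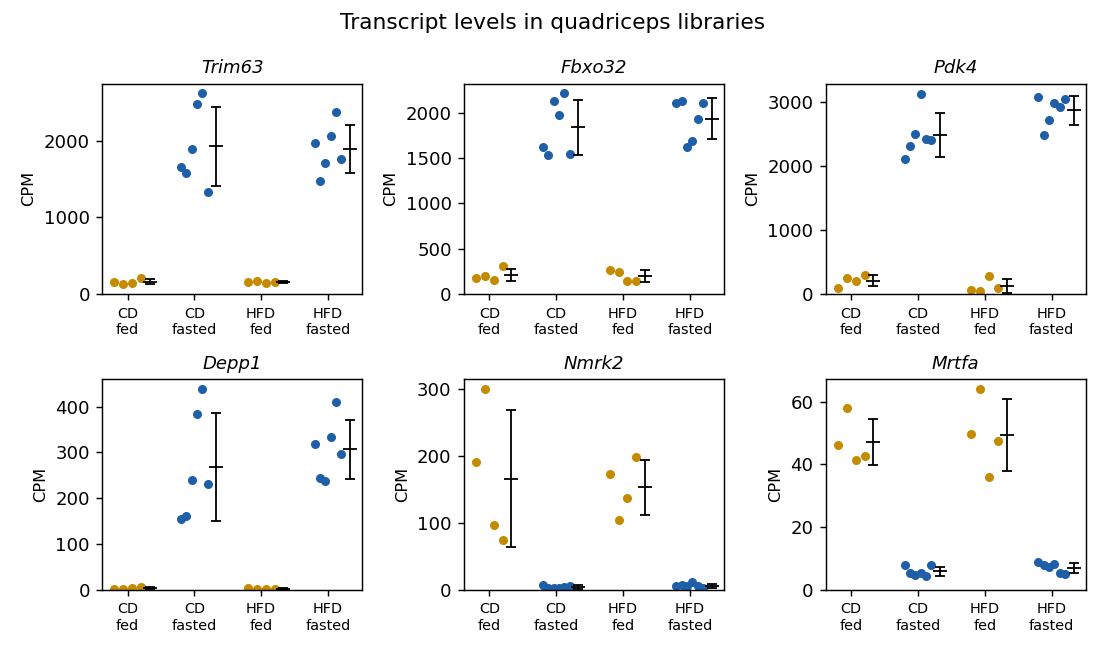
CPM of Trim63, Fbxo32, Pdk4, Depp1, Nmrk2 and Mrtfa in quadriceps, with 1 point per library in the groups CD fed (4), CD fasted (6), HFD fed (4) and HFD fasted (6) and bars for the mean ± SD. Fasted Trim63 values lie between 1337 and 2624 CPM and fed values between 132 and 214 CPM.

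Of the gene lists, the FoxO atrophy and autophagy list moved most coherently in fasted quadriceps. Of its 28 tested genes 25 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 1.36. Trim63, Fbxo32 and the translation repressor Eif4ebp1 (2.01 ± 0.10) led it. Glucocorticoid-responsive genes followed, with 19 of 22 higher and 2 lower (20 and 2 adjusted over the list alone). Among them were Fkbp5 (1.85 ± 0.12), Klf9 (1.44 ± 0.10) and Map3k6 (2.22 ± 0.15), and 5 genes belong to both lists. Against the remaining genes, camera gave adjusted p = 7.07e-42 for the FoxO list and 1.29e-24 for the glucocorticoid list. With an estimated correlation it gave 8.47e-05 and 3.06e-04. These were the only 2 of 36 tested lists that held with an estimated correlation, while 14 passed at the preset one. The fry test asks instead whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction. Neither compares the list with other genes, and fry gave adjusted p = 2.84e-12 for the FoxO list.

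Genes of fatty acid use were mostly higher. For scale, 2345 of all 12213 tested genes rose and 2243 fell, and list counts near these shares do not set a list apart. Of 33 genes of fatty acid oxidation and PPAR targets 21 rose and none fell by edgeR (22 and 0 adjusted over the list alone), with Mlycd at 1.36 ± 0.10, Ucp3 at 2.29 ± 0.19 and Acot2 at 3.48 ± 0.27. Camera gave adjusted p = 3.86e-11, and adjusted p = 0.382 with an estimated correlation. With the adipocyte marker sum as a covariate, chosen after seeing the data, 14 rose and 1 fell, and the median went from 0.44 to 0.23. That sum also holds Pnpla2 and Lipe, both higher in fasted mice, so this drop cannot be put down to fat. In one fit of all 39 libraries 7 rose. Lipolysis and lipid droplet genes gave 9 higher and 1 lower of 16 (10 and 1 adjusted over the list alone), such as Plin4 (1.81 ± 0.10), Pnpla2 (1.78 ± 0.13) and Acsl1 (0.75 ± 0.12). With the adipocyte covariate, whose sum holds 7 of these genes, 5 were higher and the median went from 0.93 to 0.21, and in the fit of all libraries 4 of 18 were higher. Of 20 genes of branched-chain amino acid catabolism 7 rose, both over all genes and adjusted over the list alone, including Bckdha (0.51 ± 0.09), Aldh6a1 (0.53 ± 0.09) and Dbt (0.60 ± 0.12). With the covariate 4 rose, and in the fit of all libraries 1. Insulin signalling genes gave 11 higher and 4 lower of 19 by either adjustment, with Foxo1 at 1.12 ± 0.13, Tbc1d1 at 1.12 ± 0.12 and Gsk3b at 0.90 ± 0.10. With the covariate 7 were higher and 4 lower, and in the fit of all libraries 5 and 1. Glycolysis genes gave 1 higher (Pfkfb3, 1.30) and 6 lower of 19, among them Pgam2 (-0.67) and Ldha (-0.43), and 0 in the fit of all libraries. Of 72 nuclear genes of oxidative phosphorylation 18 were slightly lower and 1 higher over all genes, against 6 lower adjusted over the list alone, with Ndufb7 at -0.46 ± 0.10. With the covariate 2 were lower, without a filter on low counts 11, and in the fit of all libraries 0. Lipogenesis genes split, 4 higher and 6 lower of 23 by either adjustment, with Scd2 at -2.32 ± 0.13 and Lpin1 at 1.03 ± 0.09. Their median (0.18) and mean (0.08) were positive while camera and fry pointed down, and the median was -0.32 with the covariate and -0.03 in limma voom. In the fit of all libraries 0 were higher and 4 lower. Among 23 cholesterol synthesis genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with Dhcr7 at -1.20 ± 0.13 and Fdft1 at 1.05 ± 0.09. In the fit of all libraries 4 of 24 fell and 1 rose, and with the covariate 7 of 23 fell and 1 rose.

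Matrix and interferon genes were lower in fasted muscle. Of 31 genes of extracellular matrix and fibrosis 25 fell and none rose by edgeR, both over all genes and adjusted over the list alone, including the collagen chaperone Serpinh1 (-1.65 ± 0.09), Col6a3 (-1.46 ± 0.12) and Col15a1 (-1.67 ± 0.13). Camera gave adjusted p = 2.31e-14 for this list, and adjusted p = 0.299 with an estimated correlation. In one fit of all 39 libraries 13 of 32 fell. Interferon response genes gave 12 lower of 21 by either adjustment, such as Bst2 (-0.95 ± 0.16), Stat2 (-0.78 ± 0.14) and Irf9 (-0.67 ± 0.13). With the adipocyte marker sum as a covariate 4 of 21 were lower, and in the fit of all libraries 4 of 27. Of 18 heat shock genes 10 were lower by either adjustment, among them Hspa8 (-0.54), Hspb8 (-0.45) and Cryab (-0.70), against 3 with the covariate and 3 in the fit of all libraries. Fibroblast markers gave 3 lower of 13 (5 in limma voom and 1 in the fit of all libraries) and macrophage markers 1 lower of 17 (3 in limma voom, 2 in DESeq2 and 0 of 27 in the fit of all libraries). Over all tested genes 2243 of 12213 were lower. Smooth muscle and pericyte markers gave 6 lower of 9, with Acta2 at -0.95 ± 0.12, and 2 of 11 in the fit of all libraries. Fast fibre markers, the main cell type here, gave 4 lower of 17, against 1 with the covariate or without a filter on low counts and 0 in the fit of all libraries. With the GC and length offset 2 were higher and 1 lower, and in limma voom 2 and 5. Their sum was 265064 ± 11803 CPM (SD, n = 6) in CD fasted and 283029 ± 31614 CPM (n = 4) in CD fed libraries. Ribosomal protein genes did not move as a group (1 higher and 1 lower of 52 over all genes, 0 adjusted over the list alone, edgeR). The myogenic factor Myod1 fell (-2.18 ± 0.12), as did the imprinted gene Mest (-1.31 ± 0.37; edgeR adjusted p = 0.00588), while the imprinted Peg3 rose (2.71 ± 0.24).

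**Figure D3:**
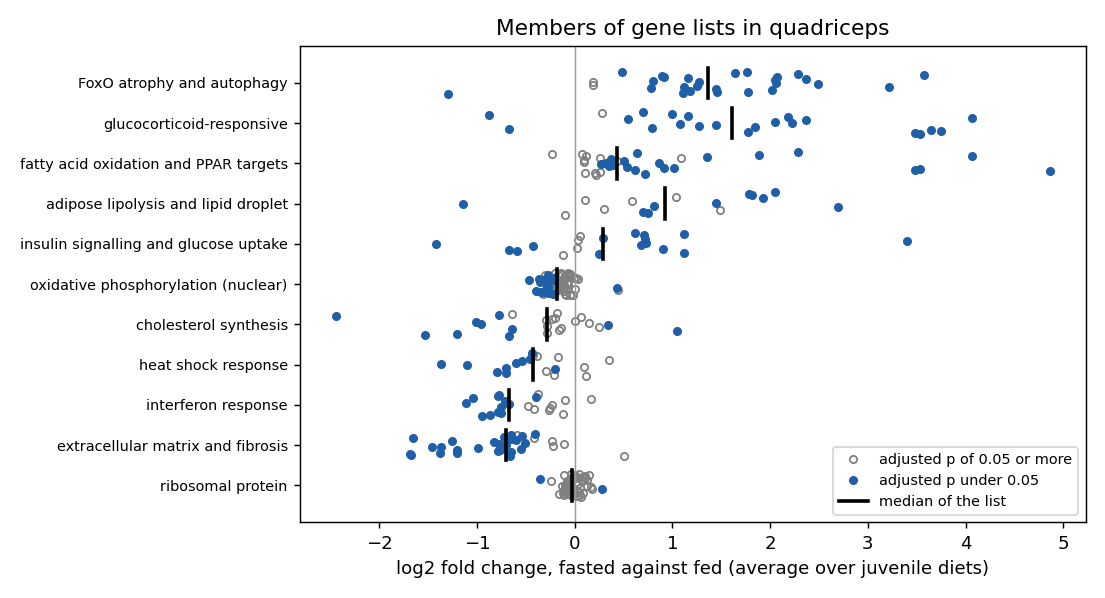
Log2 fold change of fasted against fed quadriceps (average over juvenile diets) for the members of 11 gene lists, 1 point per gene, filled where the adjusted p is under 0.05, with a black bar at the median of the list. FoxO and glucocorticoid members lie mostly to the right (medians 1.36 and 1.61) and extracellular matrix members to the left (median -0.70).

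Clock and stress regulators changed in both directions. Of 19 clock genes 8 rose and 7 fell (8 and 8 adjusted over the list alone), with Per1 at 2.18 ± 0.17 and Cry2 at 1.14 ± 0.09. In one fit of all 39 libraries 4 rose and 3 fell. The unfolded protein and amino acid response split into 8 higher and 10 lower of 25 by either adjustment, with Ppp1r15a at 1.98 ± 0.13 and Ddit3 at -1.30 ± 0.18. The list's median was -0.09 and its mean 0.05, with camera pointing down. With the adipocyte marker sum as a covariate 5 were higher and 5 lower, and in the fit of all libraries 3 and 1. Adipocyte markers rose in part, 7 of 20 by either adjustment with none lower by edgeR, including Lipe (1.44 ± 0.24) and Fabp4 (0.81 ± 0.21). In the fit of all libraries 2 were higher. Of the 20 genes 7 are also on the lipolysis list. The adipocyte marker sum averaged 2711 ± 670 CPM (SD, n = 6) in CD fasted, 1629 ± 418 CPM (n = 4) in CD fed, 2009 ± 387 CPM (n = 6) in HFD fasted and 1547 ± 254 CPM (n = 4) in HFD fed quadriceps. With this sum as a covariate Cidea was no longer past the threshold (1.69), whereas with the sum of Adipoq, Cfd, Plin1 and Retn it passed (2.49 ± 0.75; edgeR adjusted p = 0.018). Both covariates were chosen after seeing the data. Brown and beige markers split into 3 higher and 3 lower of 9, with Ppargc1a at -0.82 ± 0.14. Their median was -0.20 and their mean 1.00, with camera pointing down. With the covariate 0 were higher and 1 lower, in limma voom 0 and 3, and in the fit of all libraries 3 and 1 of 11. Adipoq (1.86 ± 0.77), Scd1 (1.87 ± 0.79), Fasn (0.70 ± 0.49), Lep (-0.19 ± 0.61) and Sfrp5 (-0.30 ± 0.25) did not pass in edgeR, with adjusted p from 0.068 for Adipoq to 0.839 for Lep.

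The fasting response of quadriceps was close in size after either juvenile diet. Trim63 rose by 3.58 ± 0.20 after juvenile CD and by 3.58 ± 0.20 after juvenile HFD (log2 ± SE; 6 fasted and 4 fed libraries each). The amino acid transporter Slc43a1 rose by 2.88 ± 0.16 and 3.15 ± 0.16, the cholesterol transporter Npc1 by 1.90 ± 0.12 and 2.12 ± 0.12, and Tacc2 by 2.39 ± 0.16 and 2.32 ± 0.16. Mrtfa changed by -2.99 ± 0.18 and -2.82 ± 0.18, Tnfaip2 by -2.77 ± 0.17 and -2.59 ± 0.17, and Sec14l5 by -2.58 ± 0.18 and -2.36 ± 0.18. Eif4ebp1 (1.99 ± 0.14), Slc41a3 (-2.05 ± 0.15) and Myod1 (-2.30 ± 0.18) were among the 5 smallest p per direction after juvenile CD. After juvenile HFD Tmem140 (2.78 ± 0.19), Serpinh1 (-1.62 ± 0.13) and Scd2 (-2.26 ± 0.19) took these places. In edgeR 2735 genes passed after juvenile CD (1469 higher, 1266 lower) and 2619 after juvenile HFD (1434 higher, 1185 lower). In one fit of all 39 libraries the counts were 439 and 476, and with the adipocyte marker sum as a covariate 1479 and 2284. Tested directly, the interaction of juvenile diet and fasting called 0 of 12213 genes in edgeR (smallest adjusted p = 0.723; 300 at an unadjusted p under 0.05), 2 in DESeq2 and 0 in limma voom; without CD fed replicate 4 or HFD fed replicate 3 edgeR called 1. On simulated data the same test recovered 26.9% of 2-fold and 74.2% of 4-fold differences.

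After a week of juvenile HFD 3 transcripts differed in adult quadriceps (10 HFD and 10 CD libraries), all of low abundance and all outside the naming rule, so they were chosen after their values were seen. Med19, a subunit of the Mediator complex of transcription (ENSMUSG00000027080, 2:84678402-84688215), averaged 3.77 ± 0.65 CPM (SD, n = 6) in HFD fasted and 1.82 ± 0.53 CPM (n = 6) in CD fasted libraries. In fed ones it averaged 5.33 ± 1.24 CPM (n = 4) and 3.28 ± 0.51 CPM (n = 4). It was 1.83-fold higher after juvenile HFD (0.87 ± 0.16 SE; edgeR adjusted p = 0.0389), and 10 of 10 HFD libraries lay above the CD mean. Gm22009, a small Cajal body RNA gene inside Kpna4 (ENSMUSG00000089417, 3:69085105-69085447), was 4.96-fold lower (-2.31 ± 0.39; edgeR adjusted p = 0.0303). In fasted libraries it averaged 0.54 ± 0.41 CPM (SD, n = 6) after HFD and 4.13 ± 2.40 CPM (n = 6) after CD, and 10 of 10 HFD libraries lay below the CD mean. The processed pseudogene Gm37009 (ENSMUSG00000103880, 3:65506277-65506637) was 2.18-fold lower (-1.12 ± 0.18; edgeR adjusted p = 0.0123). In fed mice alone it was the single gene that passed (-1.59 ± 0.28; edgeR adjusted p = 0.0473). Of its 31-mers 84.0% also occur in transcripts of other genes. Reads aligned to more than 1 place were left out of the counts, so whether its counted reads stem from those genes is not known. For the average over feeding states DESeq2 called 21 genes, limma voom 2, edgeR without a filter on low counts 6 and edgeR in one fit of all 39 libraries 0. Over 29 settings Gm37009 passed in 26, Med19 in 13 and Gm22009 in 12. In edgeR 0 genes passed without HFD fed replicate 4 or CD fed replicate 2 and 5 without CD fed replicate 4. Only 1 passed without CD fasted replicate 2, 3, 4 or 5, CD fed replicate 1, HFD fed replicate 1 or 3, or HFD fasted replicate 2 or 3. In fed mice DESeq2 called 3 and limma voom 0, and edgeR called 0 with 1 surrogate variable, in the fit of all libraries, with the adipocyte covariate or with the GC and length offset. Leaving out libraries, edgeR called 2 without CD fed replicate 4, and 0 without CD fed replicate 2, CD fasted replicate 3, 4 or 6, HFD fed replicate 1, 2 or 4, or HFD fasted replicate 1, 3, 4 or 5.

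Among the named metabolic genes edgeR called none for juvenile diet in quadriceps, while DESeq2 called Per1 (-0.76), Sult1a1 (-0.48), Arrdc2 (-0.75), Nfil3 (0.55), Ndufa1 (-0.46) and mt-Nd6 (-1.46). In edgeR Per1 passed without CD fed replicate 3 (-0.86), Nfil3 without a filter on low counts (0.56) and mt-Nd6 with the adipocyte marker sum as a covariate (-1.67). The clock and glucocorticoid gene Per1 was lower by the list-alone adjustment (-0.75 ± 0.16), with Sult1a1 (-0.48 ± 0.11) and Arrdc2 (-0.74 ± 0.19). The glucocorticoid list gave 0 of 22 over all genes and 4 lower adjusted over the list alone in edgeR (camera adjusted p = 8.64e-06; adjusted p = 0.201 with an estimated correlation). Endothelial markers gave 0 of 14 over all genes and 3 lower adjusted over the list alone, led by Egfl7 (-0.47 ± 0.12). Camera gave adjusted p = 9.30e-06, and adjusted p = 0.309 with an estimated correlation. Adjusted over the list alone, the clock list gave 1 higher (Nfil3, 0.55 ± 0.13) and 1 lower of 19, and oxidative phosphorylation 1 higher (Uqcr11, 0.46) and 3 lower of 72. Adipocyte markers (median -0.41), the FoxO list (median 0.01) and fatty acid oxidation (median -0.03) had 0 members past in edgeR by either adjustment. At the preset correlation 12 of 36 lists passed camera, and 0 with an estimated one. In fasted mice the diet contrast called 0 genes in edgeR (smallest adjusted p = 0.123; 881 at an unadjusted p under 0.05), 2 in DESeq2 and 0 in limma voom, and edgeR called 1 without CD fasted replicate 6. On simulated data 52.2% of 1.5-fold and 79.1% of 2-fold changes were recovered for the average diet contrast.

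For fasting in libraries labelled eWAT edgeR and limma voom called no gene. Pnpla3 changed by -3.47 ± 0.68 and Fasn by -1.98 ± 0.39 (log2 ± SE; 11 fasted and 8 fed libraries; edgeR adjusted p = 0.514 for each), and Lep by -1.86 ± 0.78 (edgeR adjusted p = 0.55). For Fasn each of the 11 fasted libraries (268 to 764 CPM) lay below each of the 8 fed ones (825 to 10440 CPM). For Lep 7 of the 11 did. Of 16603 genes edgeR called 0 (1448 at an unadjusted p under 0.05), DESeq2 91 and limma voom 0, and edgeR called 94 in one fit of all 39 libraries and 4 with 1 surrogate variable. The fit of all libraries shares 1 spread with quadriceps, so its SE for eWAT may be too small. The other genes with the smallest p were lower Col1a1 (-1.20 ± 0.28), Dcp2 and Col6a2 (-1.38 ± 0.33), and higher Thoc1 (0.89), Cops2 (0.67), Alkbh1, Clk4 and Uimc1. Adjusted over the list alone, 3 of 23 lipogenesis genes were lower (Pnpla3, Fasn and Srebf1, -0.90 ± 0.29), 4 of 24 cholesterol synthesis genes (among them Pmvk, -0.60 ± 0.14, Mvk, -0.73 ± 0.18, and Insig1, -0.89 ± 0.25), and 6 of 32 extracellular matrix genes (with Col15a1, -2.11 ± 0.51). Camera gave adjusted p = 3.43e-07 for lipogenesis and 1.54e-07 for both other lists, and with an estimated correlation adjusted p = 0.302, 0.302 and 0.540. With the epididymal and hepatocyte marker sums as covariates, a setting chosen after seeing the data, 217 genes passed in edgeR (77 higher, 140 lower), among them Pnpla3 (-3.46), Fasn (-1.91), Col1a1 (-1.36), Srebf1 (-1.06), Pdk4 (2.44) and Peg3 (2.02). Without the covariates but adjusted over the list alone, Pdk4 was higher (2.62 ± 0.72), Peg3 (2.26 ± 0.63) and Zim1 (2.73) were higher among imprinted genes, and Pik3r1 was lower (-1.20) among insulin signalling genes. Saa1 (6.45 ± 1.97) was higher on the acute phase list, and the hepatocyte transcripts of HFD fasted replicate 4 and CD fasted replicate 1 fall on the same side. At the preset correlation 15 of 40 lists passed camera, and 0 with an estimated one.

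For juvenile diet in libraries labelled eWAT edgeR and limma voom called no gene. Fasn differed by 1.00 ± 0.39 (log2 ± SE; 9 HFD and 10 CD libraries) and did not pass. The smallest p belonged to Pin4 (1.16 ± 0.29), Snrpf (0.78), Ap2s1, Cript and Grtp1 on the higher side and Evl (-0.45), Etl4, Rnps1, Mylip and Sgk1 (-1.06 ± 0.37) on the lower, all with an edgeR adjusted p of 1. EdgeR called 0 of 16603 genes (282 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0. In fed mice edgeR called 0 (1705 unadjusted), DESeq2 59 and limma voom 0. In fasted mice edgeR called 0 (3487 unadjusted), DESeq2 1078 and limma voom 0. EdgeR called 456 genes in fed and 2758 in fasted mice in one fit of all 39 libraries. This fit shares 1 spread with quadriceps, so its SE for eWAT may be too small and these counts too high. Adjusted over the list alone, 9 of 15 fast fibre genes were higher, such as Ckm (2.79 ± 1.00), Cacna1s (3.67) and Casq1 (1.60). The library HFD fed replicate 3 held most fast fibre transcript. The 72 oxidative phosphorylation genes had a median of 0.37 with 0 past by either adjustment (camera adjusted p = 6.35e-15; adjusted p = 0.695 with an estimated correlation). At the preset correlation 13 of 40 lists passed camera, and 0 with an estimated one. With this spread, 11.9% of 2-fold and 50% of 4-fold changes were recovered on simulated data.

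The interaction of juvenile diet and fasting in libraries labelled eWAT called 1397 genes in edgeR, 431 higher and 966 lower. The smallest p on the lower side belonged to Rassf4 (-2.05 ± 0.35), Col6a2 (-3.63 ± 0.69), Hoxa7 (-3.98 ± 0.76), Ccdc69 (-5.82 ± 1.13) and Srpx2 (-5.46 ± 1.10; log2 ± SE; edgeR adjusted p = 0.0366 for each). On the higher side were Ccdc70 (13.8 ± 3.03), Gm17359 (12.4 ± 2.92), Col22a1 (10.6 ± 2.48), Cep85 (2.34 ± 0.54) and Ergic2 (1.35 ± 0.32), also at adjusted p = 0.0366. The largest of these differences rests on few libraries: Ccdc70 averaged 16.04 ± 32.99 CPM (SD, n = 5) in HFD fasted and 7.84 ± 14.87 CPM (n = 4) in CD fed libraries. It averaged 0.22 ± 0.30 CPM (n = 6) in CD fasted and 0.034 ± 0.067 CPM (n = 4) in HFD fed libraries. The groups with most adipocyte transcript, CD fasted (39614 ± 32007 CPM, SD, n = 6) and HFD fed (37600 ± 38092 CPM, n = 4), stand against the groups with most epididymal transcript, CD fed (43777 ± 14888 CPM, n = 4) and HFD fasted (37907 ± 28377 CPM, n = 5), in this contrast. With the epididymal and hepatocyte sums as covariates, or in the 13 libraries with epididymal transcripts alone, edgeR called 0 genes, as did limma voom with all 19 libraries (4143 had an unadjusted p under 0.05 in edgeR; DESeq2 called 1990). On simulated data without covariates or other tissue, the edgeR test recovered 0% of 2-fold and 1.5% of 4-fold interactions with all 19 libraries. In such a fit a count of 0 would say little about differences of this size. Recovery of interactions with the covariates, in the 13 libraries or in limma voom was not simulated. In edgeR no gene passed without CD fasted replicate 1, 2 or 3, without any 1 of the 4 CD fed libraries, without HFD fasted replicate 1, or without HFD fed replicate 2 or 3. In contrast 781 passed without CD fasted replicate 4, and 2893 without HFD fasted replicate 4. The median interaction over all genes was 0.19 and moved to 0.30 under RLE scaling. Within each juvenile diet edgeR called 0 genes for fasting: after CD 2572 had an unadjusted p under 0.05 (566 in DESeq2 and 134 in limma voom past the threshold), and after HFD 3170 (932 and 6). EdgeR called 1 and 77 genes for these with the epididymal and hepatocyte covariates, and 0 and 5 with 1 surrogate variable. The fit of all 39 libraries gave 1163 and 2044 for these and 3764 for the interaction, against 0 for the interaction without a filter on low counts or with 1 surrogate variable. The spread shared with quadriceps may make the SE for eWAT too small in that fit. Without HFD fed replicate 1 edgeR called 86 genes for fasting after HFD, and 25 without HFD fed replicate 4.

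The fasting response differed between the tissues for 466 of 17083 genes in edgeR, 161 more positive in libraries labelled eWAT and 305 more positive in quadriceps. This fit shared 1 spread across tissues, while separate fits gave a coefficient of variation of 0.779 in eWAT and 0.203 in quadriceps. The SE for eWAT and the adjusted p may therefore be too small, and the SE for quadriceps too large. The muscle ligase Fbxo32 changed by 0.02 ± 0.20 in eWAT and 3.16 ± 0.23 in quadriceps (difference -3.14 ± 0.29; edgeR adjusted p = 1.65e-08). Ube4a changed by -0.36 ± 0.13 and 1.68 ± 0.13 (-2.03 ± 0.18; edgeR adjusted p = 1.47e-08). Mrtfa changed by -0.23 ± 0.18 in eWAT and -2.96 ± 0.18 in quadriceps (2.73 ± 0.26; edgeR adjusted p = 2.21e-08). The difference was also positive for Tfrc (1.87 ± 0.27), Calm2 (1.60 ± 0.25) and Pitpnc1 (1.20 ± 0.19). In quadriceps they changed by -2.44, -1.44 and -0.86, and in eWAT by -0.57, 0.16 and 0.34. It was negative for Rassf4 (-2.96 ± 0.29), Doc2b (-5.37 ± 0.57) and Kctd20 (-1.67 ± 0.18), which changed by 2.91, 4.99 and 1.76 in quadriceps and by -0.04, -0.38 and 0.09 in eWAT. Without eWAT HFD fasted replicate 1 the count was 742.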

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

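Of the tests below, the sign comparison with epididymal transcripts and the counts over other splits of the samples were fixed before their results were seen; those on Gm42418, GC content and length, shared reads and fat carried along were chosen only after the result was seen.

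The largest surprise was the interaction of juvenile diet and fasting in libraries labelled eWAT, with 1397 genes past the threshold in edgeR while no gene passed for either factor alone. On the higher side it was led by Ccdc70 (13.77 ± 3.03, log2 ± SE), Gm17359 (12.45 ± 2.92), Col22a1 (10.59 ± 2.48), Cep85 (2.34 ± 0.54) and Ergic2 (1.35 ± 0.32). On the lower side it was led by Ccdc69 (-5.82 ± 1.13), Srpx2 (-5.46 ± 1.10), Hoxa7 (-3.98 ± 0.76), Col6a2 (-3.63 ± 0.69) and Rassf4 (-2.05 ± 0.35). These values come from a direct test of the interaction, and with the marker sums as covariates edgeR called 0 genes, as did limma voom without them.

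Epididymal or liver tissue in the libraries is a candidate explanation for the interaction. Of the 1397 genes 98.9% had an interaction with the sign of their slope on the epididymal marker sum inside the groups, against 82.0% of all tested genes, and with the marker sums as covariates their median size fell from 4.55 to 1.73 while the median SE went from 1.17 to 0.85. Gm42418 taking a large share of the counts is argued against, since 1410 genes passed without it. A true interaction of diet and fasting in adipose tissue was neither shown nor excluded. Each CD fed and HFD fasted library carried abundant epididymal or hepatocyte transcripts, so the contrast cannot be separated from tissue content. The median size was 1.73 with the covariates, and 1.25 over 1346 of the 1397 genes in the 13 libraries with epididymal transcripts. These are medians of absolute values over genes called in the main fit, which noise alone keeps positive, and no gene passed in either setting. Other splits gave at least as many genes in 2 of 60 cases with the real one included (real 1397, highest other 2414). Few splits did so, but a random split called more genes than the real one, so random assignment is not excluded for the count. A split above the real count may reflect a structure of the samples beyond the groups, which was not tested in the splits.

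Single libraries lay far from their group in 6 of the 76 groups of values tested, where chance gives about 1 in 20. The epididymal sum of eWAT CD fed replicate 1 was 21510 CPM with the nearest other library at 49794 CPM. Hepatocyte sums stood out in eWAT CD fasted replicate 1 (46175 CPM, nearest 4061), CD fed replicate 1 (3441 CPM, nearest 718) and HFD fasted replicate 4 (164885 CPM, nearest 224). Lep was 74.5 CPM in eWAT HFD fasted replicate 3, with the nearest other library at 14.7 CPM. In quadriceps Depp1 was 4.16 CPM in HFD fed replicate 1 against 2.40 CPM in the nearest library, a small gap beside the fasted level of 307 ± 64.1 CPM (SD, n = 6).

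The fasting response differed between tissues for 466 genes in the fit that shares 1 spread across tissues. Among genes with a more positive change in eWAT, the largest evidence was for Mrtfa (2.73 ± 0.26), Tfrc (1.87 ± 0.27), Calm2 (1.60 ± 0.25) and Pitpnc1 (1.20 ± 0.19). These differences came mainly from falls in quadriceps (-2.96, -2.44, -1.44 and -0.86), against -0.23, -0.57, 0.16 and 0.34 in eWAT. Among genes more positive in quadriceps it was for Ube4a (-2.03 ± 0.18), Fbxo32 (-3.14 ± 0.29), Rassf4 (-2.96 ± 0.29), Doc2b (-5.37 ± 0.57) and Kctd20 (-1.67 ± 0.18). Both sets of values come from a direct test of the difference. The real split alone gave as many in 1 of 40 splits (highest other 115). Feeding state was reassigned inside each tissue, which also removes the fasting response of quadriceps. The splits therefore cannot separate a difference between tissues from a fasting response shared by both. The tissue itself, the epididymal transcripts and the wider spread in eWAT all differ between the arms and were not separated.

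The 3 transcripts that differed by juvenile diet in quadriceps form a second pattern, and reads shared with other genes are a candidate explanation for Gm37009, of whose 31-mers 84.0% (278 of 331) occur in transcripts of 93 other genes. For Gm22009 (3.8%) and Med19 (10.5%, with Zdhhc5, which changed by 0.01 ± 0.08) this stays open, since transcripts do not show unspliced reads of a surrounding gene, and 100% of the exonic bases of Gm22009 lie inside Kpna4 and 24.6% of those of Med19 inside 2 other genes. Reads aligned to more than 1 place were not counted, so the shared 31-mers of Gm37009 do not show that its counted reads were shared. A trend with GC content and length, fitted on genes with an average log2 CPM above 2, is argued against as the whole cause. With it removed Med19 went from 0.87 to 0.82 and Gm37009 stayed at -1.12. The median size of the 3 changes, which is that of Gm37009, kept 99.8% of its value. Gm22009 then lost its call (adjusted p = 0.0753 in edgeR) because its SE widened, with -2.31 ± 0.39 before and -2.39 ± 0.45 after. A lasting effect of the juvenile diet on Med19 and Gm22009 stays open as well. Of 60 splits, the real one included, 2 gave 3 genes (highest other 3). Few splits reached the real count, but another split equalled it, so chance is not excluded.

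Higher adipocyte transcripts in fasted quadriceps form the last pattern weighed. Fat carried along with the muscle is argued against for Pnpla2, whose change kept 99.3% of its size (1.77 ± 0.13) with the sum of Adipoq, Cfd, Plin1 and Retn as covariate, and for the greater part of Lipe (78.0%, 1.13 ± 0.14). For Cidec, Cebpa, Adig, Fabp4 and Pparg it may account for part, since their median change kept 48.3% of its size (1.47 to 0.71) and 4 of the 5 still passed. A rise inside muscle fibres is the biological reading left open for Pnpla2 and Lipe. With this covariate 4171 genes passed for fasting in edgeR.

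Other splits of the quadriceps libraries give the scale for the fasting counts. For the average over juvenile diets only the real split gave as many (1 of 60; real 4588, highest other 1), as after juvenile CD (1 of 60; real 2735, highest other 1) and after juvenile HFD (1 of 60; real 2619, highest other 24), so chance is excluded for these. Chance is not excluded for diet in fed mice (8 of 35; real 1, highest other 1). Diet in fasted mice (60 of 60; real 0, highest other 13) and the interaction (60 of 60; real 0, highest other 170) have a real count of 0, which any split reaches, so the splits cannot inform on chance there. Whether the split with 170 genes reflects a structure of the samples was not tested. Chance is not excluded for the number of lists at the preset correlation, with 19 of 60 splits for fasting (real 14, highest other 19) and 21 of 60 for diet (real 12, highest other 21).

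In libraries labelled eWAT any split reaches a real count of 0, so for these contrasts the splits cannot inform on chance. As many genes came from 60 of 60 splits for average diet (highest other 2124), diet in fasted mice (highest other 4601), average fasting (highest other 1001), fasting after CD (highest other 0) and fasting after HFD (highest other 162), and from 35 of 35 for diet in fed mice (highest other 0). Splits that call 1001 to 4601 genes where the real split calls 0 may reflect a structure of the samples. The uneven epididymal and liver transcripts are a candidate source that was not tested in the splits. For the number of lists chance is not excluded, as 41 of 60 splits reached the real 13 for diet (highest other 31) and 40 of 60 the real 15 for fasting (highest other 30).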

How the results depend on the processing

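The RLE, filter, DESeq2, voom, surrogate-variable, all-libraries, correlation and leave-one-out settings were planned; the epididymal-only libraries, the marker covariates, the GC and length offset and the fit without Gm42418 were chosen after seeing the data.

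The 4588 genes of the quadriceps fasting response became 4592 with RLE scaling (4574 shared), 4712 in DESeq2 (4568 shared) and 4768 in limma voom (4271 shared). Of 3973 values of named genes for this contrast 3721 stayed on their side of the threshold, 214 lost and 38 gained a call, and none reversed; in all comparisons together no gene past the threshold reversed, and sign changes of genes past it under neither setting were not counted as a direction. RLE scaling moved no count by more than 1.5 times in either tissue.

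Without a filter on low counts more genes were tested, and the counts were 0 for the eWAT interaction and 6 for average diet in quadriceps. DESeq2 gave, in eWAT, 1 gene for average diet, 59 for diet in fed mice, 1078 for diet in fasted mice, 91 for average fasting, 566 for fasting after CD and 932 after HFD, and in quadriceps 21 for average diet, 3 for diet in fed mice, 2 for diet in fasted mice and 2 for the interaction. Limma voom gave in eWAT 134 for fasting after CD, 6 after HFD and 0 for the interaction, and 0 for diet in fed mice in quadriceps. With 1 surrogate variable the eWAT counts were 4 for average fasting, 5 for fasting after HFD and 0 for the interaction, and 0 for diet in fed mice in quadriceps. For these 3 tools the cause was not tested.

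All 39 libraries in one fit share 1 spread across tissues, so the SE may be too small for eWAT and too large for quadriceps. The eWAT counts were then 456 for diet in fed mice, 2758 in fasted mice, 94 for average fasting, 1163 after CD, 2044 after HFD and 3764 for the interaction. Those of quadriceps were 0 for average diet, 0 for diet in fed mice, 1589 for average fasting, 439 after CD and 476 after HFD. An estimated correlation left 0 of 13 and 0 of 15 lists in eWAT (diet, fasting) and 0 of 12 and 2 of 14 in quadriceps.

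The 13 epididymal libraries alone gave 0 genes for the eWAT interaction, with fewer samples. Epididymal and hepatocyte covariates gave 217 for average fasting, 1 after CD, 77 after HFD and 0 for the interaction. The adipocyte covariate in quadriceps gave 3016 for average fasting (2856 shared), 1479 after CD and 0 for diet in fed mice, and the GC and length offset gave 0 for diet in fed mice; the cause was not tested.

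Leaving out each library in turn gave, in eWAT, 0 to 86 genes for fasting after HFD (86 without HFD fed replicate 1), 0 to 2893 for the interaction, and 0 for each of the other 5 contrasts. In quadriceps the range was 4273 to 4564 for average fasting, 2131 to 2949 after CD, 2098 to 2638 after HFD, 0 to 5 for average diet, 0 to 2 for diet in fed mice, 0 to 1 in fasted mice and 0 to 1 for the interaction. The tissue difference ranged from 317 to 742. Over 29 settings Gm37009 passed in 26, Med19 in 13 and Gm22009 in 12 for average diet, with adjusted p from 6.77e-06 to 0.53, 0.0014 to 1 and 3.23e-06 to 0.707.

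No paired analysis was run because the labels do not say which eWAT and quadriceps libraries share a mouse. The libraries of both tissues are listed in nearly the same order of groups, but a match by this order was not tried. Depth limits low transcripts such as Gm22009, which lay between 0 and 8.05 CPM in quadriceps.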

Other observations

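The comparison of adipocyte transcripts with each other, and both hypotheses below, were chosen only after the result was seen.

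Among adipocyte transcripts, leptin differed most by feeding state in libraries labelled eWAT, once each transcript was set against the mean of the other 19 listed ones in its own library. Relative Lep was -2.64 ± 1.42 (log2, SD, n = 11) in fasted and -0.08 ± 0.31 (n = 8) in fed libraries, a difference of -2.56 (exact permutation within juvenile diets, adjusted p = 0.00177). The highest fasted value, -0.87, lay below the lowest fed value, -0.48. Differences here are averages of those within each juvenile diet, while the levels pool both diets. Pnpla2, the first lipase of fat breakdown, was higher by 0.92 (1.88 ± 0.52 against 0.99 ± 0.31; exact permutation adjusted p = 7.56e-04), as were Fabp4 by 0.82 (exact permutation adjusted p = 0.00177), Pparg by 0.42 (0.0219) and Adipoq by 0.40 (0.0301), while Plin1 differed by -0.69 (0.0212). Of the 20 transcripts 6 passed and 10 had an unadjusted p under 0.05. The smallest p that the 26460 arrangements can give is 3.78e-05.

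A lower leptin transcript per adipocyte transcript in fasted mice, whatever the share of adipose tissue in a library, stays a hypothesis, since the values that prompted it (adjusted p = 0.00177) are the same ones tested. Transcripts of other tissues that are also on the list could still enter the ratios, since Rbp4, made in liver as well, reached 6.22 in 1 fasted library. By juvenile diet 0 of the 20 relative transcripts passed in the exact permutation test over 32340 arrangements, and 0 had an unadjusted p under 0.05. The smallest adjusted p was 0.99, so another adipocyte profile after juvenile HFD cannot be told apart from none with 9 HFD and 10 CD libraries of this spread.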
